A study of Mus musculus with 12 samples.

How the data were processed

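Livers of 12 female mice were snap frozen and ground to powder, and total RNA was depleted of ribosomal RNA and made into Illumina libraries, per the labels' protocols. The deposited table holds 1 column per library, matched to its sample by the description in the labels, and 22557 genes with Ensembl identifiers, coordinates and biotypes. Its unit is a normalized signal: the authors divided the estimated reads of each gene by a size factor per library, as the deposited table's naming states, and did not log-transform them. STAR 2.7.8a, Partek and DESeq2 are named in the submitters' processing notes, with genome build mm39. The program that counted reads, the annotation release, any filter and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. No column was left unmatched to a sample.

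The value of 1 read was taken in each library as the step that low values repeat at least 20 times. Between 73.1% and 75.5% of values up to 20 reads were whole multiples of it within 0.01 reads, and the rest were fractions of reads, so whole reads were not recovered for nearly all genes and no count model was used. Dividing each library's total by its step gave the estimated depths of 12700000 to 43000000 reads.

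Genes with a value of at least 10 in at least 3 libraries, 17380 in all, were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). All 12 libraries entered 1 fit with a mean per group, so that the 4 groups of 3 share an estimate of the spread, and no covariate or block was used. There were 6 comparisons: KO against WT without and with a tumour, tumour against none in WT and in KO, the genotype by tumour interaction, and KO against WT averaged over tumour states. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The median standard error of a log2 fold change was 0.5 in the comparisons of a pair of groups. Replicates were different mice, per the labels.

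The comparisons, the tests, the naming rule, 42 gene lists and most alternatives were fixed before the data were examined. Of 786 symbols on the lists 757 were found in the table, and 41 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation beside it and fry as an alternative. Named genes were 10 fixed genes of lipid metabolism, inflammation and T cells with Mtdh among them; the 6 largest increases and 6 largest decreases per comparison among called genes with a mean of at least 50 and no overlap between groups, without unnamed gene models; up to 4 members, by smallest p, of each called list; and up to 2 members past the gene test of any other list. For the interaction and the averaged comparison they were up to 6 called genes by smallest p with a mean of at least 50. Some genes that the rule names are not reported here. List scores were also compared by an exact permutation of genotype labels within each tumour state, 400 relabellings in all.

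The alternatives were a pseudocount of 10, no filter on low values, values rescaled to the same total, quantile normalization, the 6 libraries of a comparison fitted alone, robust eBayes, library weights, the replicate number as a block, and each library left out in turn. Leaving out both libraries that stood apart, testing protein-coding genes alone and testing lists under both rescalings were added after the data were seen. The gene and list tests were tested on simulated data made for the comparison of tumour against none in WT with 17380 genes: 16%, 56%, 76% and 88% of 50 genes were recovered at log2 changes of 1, 2, 3 and 4, 7 of 17180 unchanged genes were called, and 5 of 5 lists shifted by 1 and 0 of 36 unchanged lists were called. The simulated genes varied independently of each other, whereas members of real lists were correlated (estimated at 0.754 for mitochondrially encoded genes). The simulation therefore does not show how often the preset correlation calls unchanged lists in these data. Transcript sequences were compared with Biopython 1.88 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.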

Results

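RNA sequencing of whole liver was carried out for 12 female mice, wild type (WT) or with a knockout (KO) of Mtdh, with or without a Py8119 mammary tumour. Mtdh encodes metadherin, a protein studied for its part in tumour growth and metastasis, and Py8119 is a mouse mammary tumour cell line. The series addresses how Mtdh of the host acts on lipid metabolism in the liver and on CD8 T cells during tumour growth. Each of the 4 groups held 3 libraries from different mice: WT_no_tumor, KO_no_tumor, WT_tumor and KO_tumor. The deposited values were taken to be reads divided by a size factor per library. The value of 1 read, taken from the steps between low values, gave estimated depths of 12700000 reads in KO_tumor replicate 1 and 25700000 to 43000000 in the other 11 libraries, to 3 digits. In all, 17380 of 22557 genes passed the filter on low values and were tested. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Adjusted p-values of single genes came from limma and those of gene lists from camera, each with Benjamini-Hochberg adjustment.

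A pair of libraries stood apart from the rest. KO_tumor replicate 1 had the lowest depth and 14899 genes above 0, against 17772 to 20365 in the other libraries. Its mean correlation with the other libraries was 0.831, against 0.887 to 0.926. KO_no_tumor replicate 3 had 4.84% of its signal in small nucleolar RNAs and 5.32% in small nuclear RNAs, against at most 1.23% and 2.05% elsewhere. Its protein-coding share was 83.7%, against 92.2% to 95.7%. Albumin, the main plasma protein made by hepatocytes, took 6.1% to 12.3% of the signal in each library. Correlations between libraries were computed across genes, which are not independent replicates.

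**Figure D1:**
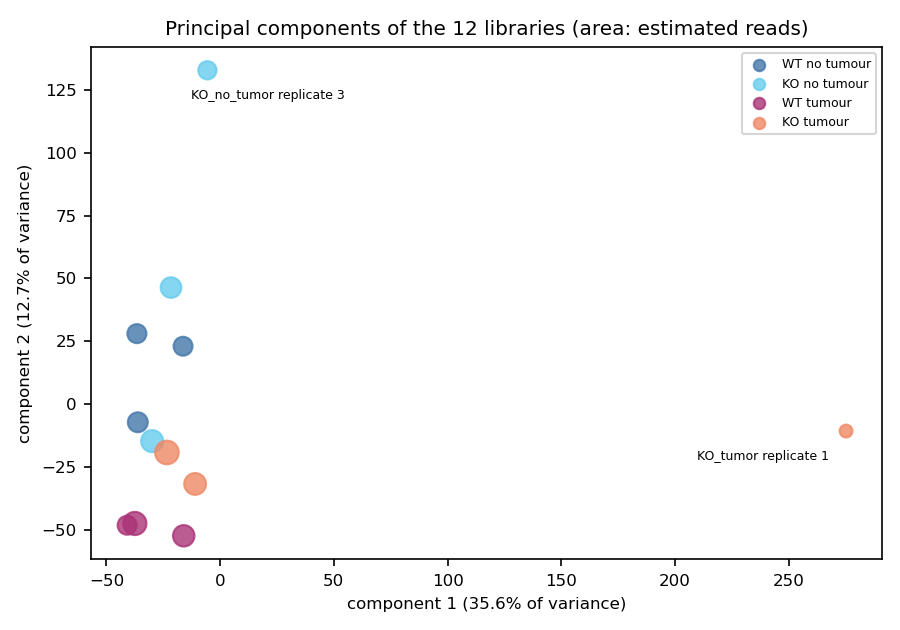
First and second principal components of the log2 values of 17380 genes, which carried 35.6% and 12.7% of the variance. Each point is a library coloured by group, its area follows the estimated reads, and KO_tumor replicate 1 lies at 275.2 on the first component.

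Mtdh (ENSMUSG00000022255, chromosome 15, 34082840 to 34145770, mm39) was measured first in every library. The WT_no_tumor values were 4330, 5370 and 4970, and the WT_tumor values were 5290, 3950 and 5700. The KO_no_tumor values were 584, 436 and 627, and the KO_tumor values were 1060, 380 and 323. The group means were 4890 ± 527 and 4980 ± 914 in WT and 549 ± 100 and 589 ± 412 in KO, without and with a tumour (SD, n = 3). The KO means were 11.2% of the WT mean without a tumour and 11.8% with a tumour, and every KO library lay below every WT library. Mtdh fell in KO livers by 3.16 ± 0.35 (SE) on the log2 scale without a tumour (limma adjusted p = 0.0046), and by 3.28 ± 0.35 with a tumour (limma adjusted p = 0.00301). The first of these calls ended without WT_no_tumor replicate 2 (limma adjusted p = 0.0657) or KO_no_tumor replicate 2 (limma adjusted p = 0.0519). The second ended with the 6 libraries fitted alone (limma adjusted p = 0.114). The tumour left no detectable change in Mtdh in WT livers (0.01 ± 0.35) or KO livers (−0.10 ± 0.35).

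**Figure D2:**
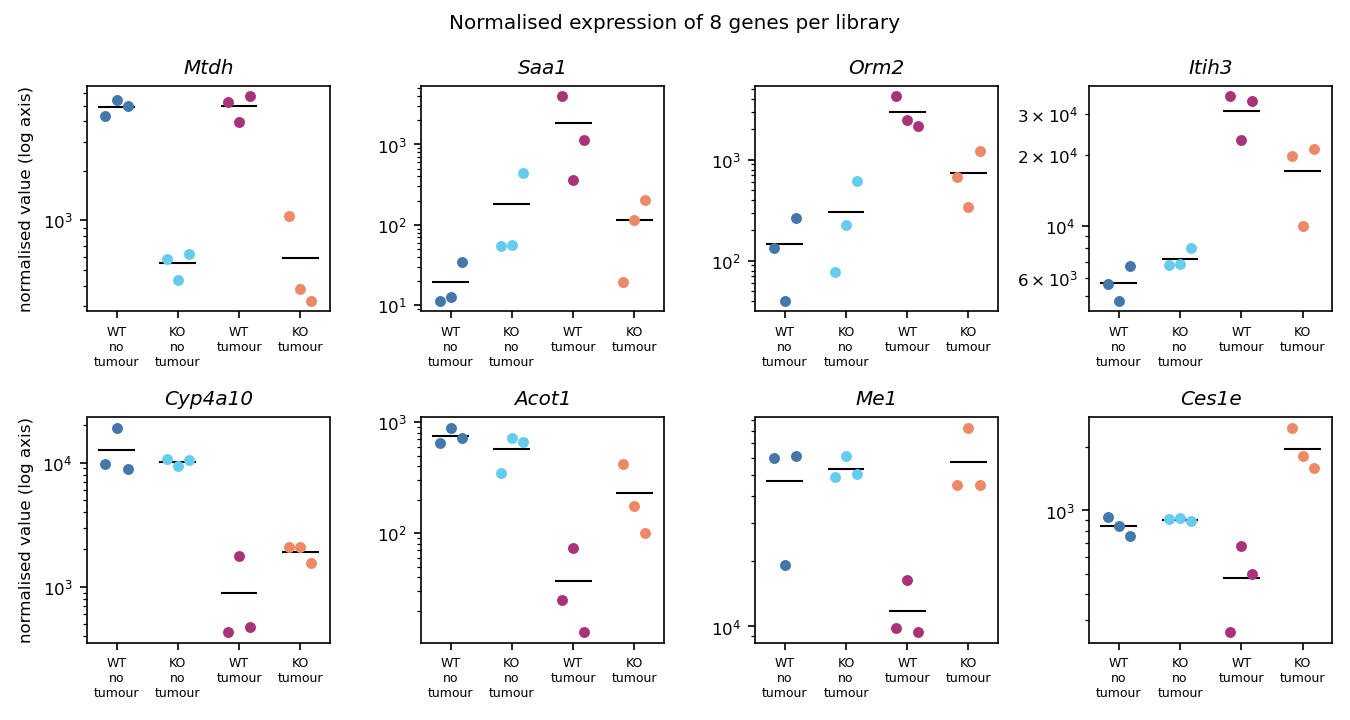
Deposited values (normalized signal, log axis) of Mtdh, Saa1, Orm2, Itih3, Cyp4a10, Acot1, Me1 and Ces1e in the 4 groups. Each point is a library and each bar the group mean; the Mtdh means were 4890 and 4980 in WT and 549 and 589 in KO.

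In livers without a tumour, Mtdh was the gene past the limma threshold, and gene lists of liver metabolism and of immune cells lay somewhat higher in KO by camera with a preset correlation. Of 41 lists, 14 passed in this way, while 0 passed with an estimated correlation and 0 with fry, and the interferon and antigen presentation lists moved with KO_no_tumor replicate 3. Other splits of the 6 libraries called a median of 12 lists and at most 14, so the count of 14 does not stand out from arbitrary groupings. Genes of bile acid synthesis and transport had 17 of 20 members positive with a median log2 fold change of 0.33, among them Slc27a5 (0.52 ± 0.21, SE) and Baat (0.47 ± 0.21), of the pathway that joins bile acids to amino acids. Genes of xenobiotic metabolism had 21 of 23 members positive with a median of 0.27, such as the cytochrome P450 Cyp2c50 (0.84 ± 0.36) and the nuclear receptor gene Nr1i3 (0.51 ± 0.26). Markers of B and plasma cells had 12 of 12 members positive with a median of 1.41, such as Cd79b of the B cell receptor (3.02 ± 1.32), Cr2 (1.86 ± 0.82) and Ighm (1.67 ± 0.84).

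These 3 lists lay above the other genes with camera at a preset correlation of 0.01 (camera adjusted p = 6.57e-05, 7.44e-05 and 2.92e-06). With an estimated correlation their adjusted p was 0.082, 0.059 and 0.23. Each of the 14 lists that passed with the preset correlation had a positive median, whereas 3 lists passed as lower without WT_no_tumor replicate 2, 2 without KO_no_tumor replicate 3 and 1 without WT_tumor replicate 2. Of the lists' members, Mtdh being on none of them, 0 passed limma over all genes, and 1 passed adjusted over the list alone: Clec4e, a receptor of myeloid cells, on the neutrophil list (4.82 ± 1.07). The neutrophil list had a median of 0.49 (adjusted p = 0.57 with an estimated correlation), and its preset call ended without WT_no_tumor replicate 1 (median 0.02) or KO_no_tumor replicate 1 (median 0.10), while the median was 0.90 without WT_no_tumor replicate 3 and 0.29 with a pseudocount of 10.

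Antigen presentation genes (16 of 17 positive, median 0.78) and interferon-stimulated genes (24 of 26 positive, median 0.63) also passed with the preset correlation, and both had an adjusted p of 0.57 with an estimated correlation. Members included Nlrc5, the activator of MHC class I genes (1.09 ± 0.45), Tap1 (1.22), Irf1 (0.94) and Gbp2 (1.22). Both lists moved with KO_no_tumor replicate 3, the library rich in small nuclear RNAs. Its interferon score was 1.72 and its antigen presentation score 1.58. The other KO_no_tumor libraries scored −0.55 and −0.04 for interferon and −0.63 and −0.17 for antigen presentation. Without that library the medians were −0.01 for interferon and 0.20 for antigen presentation, and both calls ended. The call of the acute phase list (26 of 30 positive, median 0.28; adjusted p = 0.57 with an estimated correlation) also ended without it (median 0.14). Without KO_no_tumor replicate 1 the medians were 1.12 for interferon, 1.28 for antigen presentation and 0.48 for the acute phase.

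The remaining lists that passed with the preset correlation had smaller support. Erythroid genes had a median of 0.57, with an adjusted p of 0.36 with an estimated correlation, and the call ended without WT_no_tumor replicate 2 or 3 or KO_no_tumor replicate 2. Lipoprotein genes (median 0.26), amino acid and urea cycle genes (0.23), monocyte and macrophage markers (0.26), hepatocyte core genes (0.14) and pericentral genes (0.32) each had an adjusted p of 0.57 with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of 0.22 (adjusted p = 0.59 with an estimated correlation). Of these, the lipoprotein list kept its preset call with every single library left out. Without WT_no_tumor replicate 3 the calls of the amino acid and urea cycle, hepatocyte core and oxidative phosphorylation lists ended, and without KO_no_tumor replicate 1 that of the amino acid and urea cycle list. The monocyte call ended without WT_no_tumor replicate 1 or 2 or KO_no_tumor replicate 2 or 3, the hepatocyte core call also without KO_no_tumor replicate 2 or 3, and the pericentral call without WT_no_tumor replicate 2. Medians moved by over 1.5 times without WT_no_tumor replicate 1 (monocytes 0.16, hepatocyte core 0.22), WT_no_tumor replicate 2 (erythroid 0.28, pericentral 0.18) or WT_no_tumor replicate 3 (amino acid 0.04, monocytes 0.54, hepatocyte core 0.04). They also did so without KO_no_tumor replicate 1 (amino acid 0.07, monocytes 0.48, hepatocyte core 0.22), KO_no_tumor replicate 2 (lipoprotein 0.17, amino acid 0.46, monocytes 0.48) or KO_no_tumor replicate 3 (monocytes 0.17). The hepatocyte core median was 0.09 with values rescaled to the same total and 0.07 with quantile normalization, which ended the call (camera adjusted p = 0.148).

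No genes were higher and 1 gene, Mtdh, was lower in KO livers without a tumour by limma over all genes. At an unadjusted p under 0.05 there were 336 genes, against 869 expected by chance, and limma with library weights called 2. Genes are correlated and the 4 groups share an estimate of the spread, so such counts can lie far above or below that expected number. The lipid regulators fixed for naming had log2 fold changes of 0.05 ± 0.24 (Rxra), 0 ± 0.32 (Ppara), 0.05 ± 0.35 (Cpt1a), 0.52 ± 0.69 (Fasn), 0.53 ± 0.40 (Srebf1) and −0.37 ± 0.48 (Cyp7a1), each with a limma adjusted p of 1. Cd8a, a marker of cytotoxic T cells, was at 1.94 ± 1.21 and the acute phase gene Saa1 at 2.64 ± 1.02, both with a limma adjusted p of 1. The lists of fatty acid oxidation (median 0.05, camera adjusted p = 0.486), PPARα targets (0, 0.731), lipogenesis (0.26, 0.0707) and T and NK cells (−0.16, 0.365) did not pass.

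A mammary tumour elsewhere in the body was accompanied, in WT liver, by higher acute phase, endoplasmic reticulum stress, granulocyte, erythroid and matrix genes and by lower genes of fatty acid oxidation and other PPARα targets. Saa1 (ENSMUSG00000074115, chromosome 7, 46389921 to 46392404), a serum amyloid of the acute phase, rose from 19.3 ± 12.8 to 1830 ± 1900 (SD, n = 3), a log2 fold change of 6.03 ± 1.02. Orm2 (ENSMUSG00000061540, chromosome 4, 63280686 to 63284115), an acute phase plasma protein gene, rose from 146 ± 113 to 2970 ± 1130. Cyp4a10 (ENSMUSG00000066072, chromosome 4, 115375461 to 115390846), a fatty acid hydroxylase and PPARα target, fell from 12600 ± 5610 to 892 ± 761. By limma over all genes, 75 were higher and 43 lower.

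The acute phase list had 28 of 30 members positive with a median log2 fold change of 1.54 and passed with an estimated correlation (adjusted p = 0.022). Of its members, 15 passed over all genes and 22 adjusted over the list alone. Itih3 (2.43 ± 0.28, limma adjusted p = 0.00157), Steap4 (1.97 ± 0.22, 0.00157), Apcs (2.74 ± 0.40, 0.00814) and Socs3, a feedback inhibitor of cytokine signalling (2.69 ± 0.39, 0.00814), rose in WT livers with a tumour. Among the largest increases were Cpxm1 (6.21 ± 0.99, limma adjusted p = 0.0124), the siderophore-binding Lcn2 (5.67 ± 0.98, 0.0184), Orm2 (4.65 ± 0.73, 0.0116), the adhesion molecule Selp (4.22 ± 0.79, 0.0272) and the chemokine Cxcl1 (3.96 ± 0.79, 0.037). Saa1 itself had a limma adjusted p of 0.0179.

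Genes of the endoplasmic reticulum stress list had 20 of 21 members positive with a median of 1.14 (adjusted p = 0.013 with an estimated correlation), of which 3 passed over all genes and 14 adjusted over the list alone. Those 3 were Sdf2l1 (2.12 ± 0.39, limma adjusted p = 0.0238), the chaperone Hspa5 (1.17 ± 0.22, 0.0293) and the transcription factor Xbp1 (0.99 ± 0.20, 0.0369). Markers of stellate cells, fibroblasts and matrix rose as a list, with 18 of 21 members positive and a median of 0.86 (adjusted p = 0.048 with an estimated correlation). Of these, 2 passed over all genes, Col3a1 (1.5 ± 0.25, limma adjusted p = 0.015) and Dcn (1.16 ± 0.20, 0.0184), and 10 adjusted over the list alone.

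Markers of blood cells were higher in the same livers. Tested members numbered 14 of 19 listed for neutrophils, 5 of 13 for granulocyte precursors and 11 of 20 for erythroid genes. A gene could pass the filter on low values through the 3 WT_tumor libraries alone, which favours positive members here in advance. It likewise favours negative members of these lists in KO against WT with a tumour and in the interaction. The neutrophil list had 14 of 14 members positive with a median of 2.65 (adjusted p = 0.029 with an estimated correlation), and of 1.5 with a pseudocount of 10. Over all genes 1 passed, Lrg1 (3.18 ± 0.43, limma adjusted p = 0.00499), which hepatocytes also make, and 8 adjusted over the list alone, among them Clec4e (4.88) and Mmp9 (3.98). Granulocyte precursor markers had 5 of 5 members positive with a median of 1.35 (adjusted p = 0.029 with an estimated correlation). Of them 0 passed limma over all genes and 2 adjusted over the list alone, Prtn3 (7.15 ± 1.65) and Chil3 (4.71). Erythroid genes had 11 of 11 members positive with a median of 1.64 (adjusted p = 0.016 with an estimated correlation). Of these genes 1 passed over all genes, Alas2 of haem synthesis (1.60 ± 0.33, limma adjusted p = 0.0422), and 7 adjusted over the list alone. Monocyte and macrophage markers had 14 of 17 members positive with a median of 0.99 (adjusted p = 0.069 with an estimated correlation), and a median of 0.64 without WT_tumor replicate 2. Their member Ccr2, a chemokine receptor, rose by 1.78 ± 0.37 (limma adjusted p = 0.0448). T and NK cell markers had a median of 0.06 (camera adjusted p = 0.641), and Cd8a was at 2.42 ± 1.21 (limma adjusted p = 0.626). Markers of mammary tumour epithelium had a median of 0.76 with 7 of 9 members positive and did not pass (camera adjusted p = 0.236).

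Genes of fatty acid breakdown moved the other way. PPARα targets had 17 of 20 members negative with a median of −1.04 (adjusted p = 0.022 with an estimated correlation). Of these, 6 passed over all genes and 9 adjusted over the list alone. Acot1 (−4.64 ± 0.59, limma adjusted p = 0.00321) and Acot3 (−4.11 ± 0.45, 0.00157), acyl-CoA thioesterases, and Cyp4a10 (−4.06 ± 0.43, 0.00157) and Cyp4a14 (−3.17 ± 0.55, 0.0184) were lower in WT livers with a tumour. Genes of fatty acid oxidation had 19 of 20 members negative with a median of −0.54 (adjusted p = 0.048 with an estimated correlation). Over all genes 1 of them passed, Decr1 (−1.27 ± 0.22, limma adjusted p = 0.0201), and 10 adjusted over the list alone, such as Acaa1b (−1.97) and Cpt2 (−0.89). Cpt1a, which carries long fatty acids into mitochondria, was at −0.40 ± 0.35 (limma adjusted p = 0.875), Ppara at −0.65 ± 0.32 (0.628) and Rxra at 0.02 ± 0.24 (1).

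Xenobiotic metabolism and growth hormone dependent, sex-biased genes also fell as lists. The first had 17 of 23 members negative with a median of −0.48 (adjusted p = 0.016 with an estimated correlation). Its members past the test were 1 over all genes, Aldh3a2 (−2.06 ± 0.33, limma adjusted p = 0.0124), and 4 adjusted over the list alone. The second had 20 of 23 members negative with a median of −0.85 (adjusted p = 0.016 with an estimated correlation). Of its members 4 passed over all genes and, adjusted over the list alone, 8 lower and 1 higher. Its members A1bg (−5.82 ± 1.11, limma adjusted p = 0.0293), Sult2a1 (−3.63 ± 0.71, 0.0356), Mup3 (−1.72 ± 0.34, 0.0359) and Cish (−1.22 ± 0.25, 0.0432) were lower. Hamp2, a hepcidin-like gene, fell from 2300 ± 597 to 240 ± 324 (−4.29 ± 0.70, limma adjusted p = 0.0149). Retsat, of retinol metabolism, fell by 2.37 ± 0.35 (limma adjusted p = 0.00814) and the lipase gene Lipc by 1.32 ± 0.25 (0.0265), while Igfbp1 rose (3.33 ± 0.62, 0.0261).

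Of the 41 lists, 27 passed in WT livers with the preset correlation, 17 higher and 10 lower, and the 10 described as passing with an estimated correlation kept their preset call with every single library left out. Lipogenesis had 18 of 20 members negative with a median of −0.62 (adjusted p = 0.33 with an estimated correlation), with Fasn at −0.12 ± 0.69, Srebf1 at 0.49 ± 0.40 and Me1 at −1.85 ± 0.41 (limma adjusted p = 0.061). Nuclear oxidative phosphorylation genes had a median of −0.35 (adjusted p = 0.31 with an estimated correlation), mitochondrially encoded genes −0.75 (0.23) and bile acid genes −0.34 (0.065), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at −0.37 ± 0.48. NF-κB targets and chemokines had a median of 0.75 (adjusted p = 0.14 with an estimated correlation), immediate early genes 0.92 (0.12), endothelial markers 0.39 (0.18) and Kupffer cell markers 0.49 (0.41). Cholesterol synthesis genes had a median of 0.39 (adjusted p = 0.65 with an estimated correlation), and −0.04 without WT_no_tumor replicate 2. Preset calls ended without WT_tumor replicate 3 for oxidative phosphorylation and cholesterol synthesis, without WT_no_tumor replicate 2 for Kupffer cells and without KO_tumor replicate 1 for cholesterol synthesis (camera adjusted p = 0.0551). The lipogenesis median was −0.27 without WT_no_tumor replicate 1 and −1.15 without WT_no_tumor replicate 2. Without WT_no_tumor replicate 1 the medians were also 0.46 for NF-κB targets, −0.22 for oxidative phosphorylation, −0.20 for bile acid genes and 0.61 for cholesterol synthesis. They were 0.28 for Kupffer cells and 0.23 for endothelial markers without WT_no_tumor replicate 2, and 0.79 for Kupffer cells without WT_no_tumor replicate 3. Without a WT_tumor library, immediate early genes were at 0.55 (replicate 1), mitochondrially encoded genes at −0.45 (replicate 2), and oxidative phosphorylation at −0.22 and cholesterol synthesis at 0.24 (replicate 3). Quantile normalization gave −0.23 for oxidative phosphorylation and −0.21 for bile acid genes.

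The count of 118 genes depended on single libraries: it was 18 without WT_no_tumor replicate 1, 18 without WT_no_tumor replicate 2, 67 without WT_no_tumor replicate 3, 21 without WT_tumor replicate 1, 12 without WT_tumor replicate 3 and 205 without KO_tumor replicate 1. It was 212 without both libraries that stood apart and 510 with library weights. Of the 34 genes named under the rule that passed in this comparison, 6 to 34 kept their call with a single library left out and 0 changed direction. Acot1, Acot3, Cyp4a10, Steap4, Itih3 and Lrg1 kept theirs in all 22 alternative settings. Saa1, Orm2, Cyp4a10, Acot1, Acot3, Hamp2, Sult2a1, Mup3 and the globin genes belong to families of similar sequence, and how reads were shared among members is not given in the sources used here, so values of single members are uncertain.

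**Figure D3:**
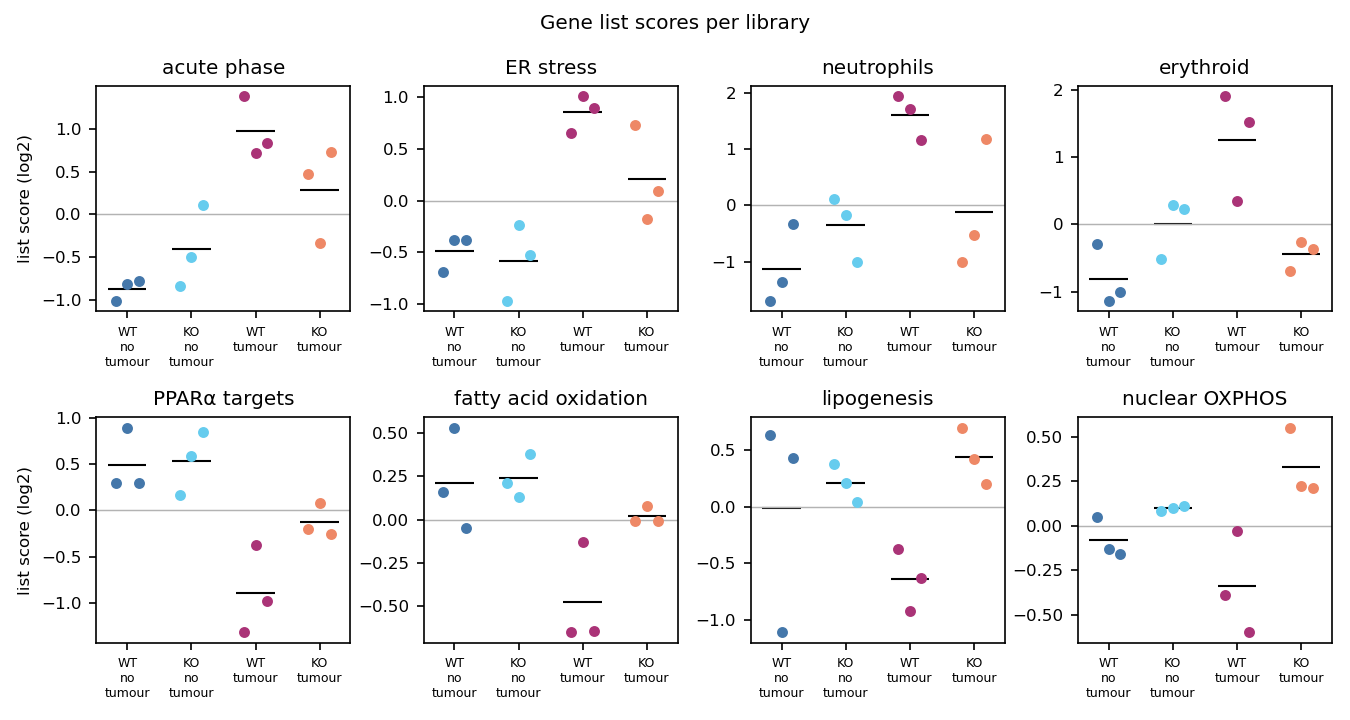
Scores of 8 gene lists per library (mean over members of the log2 value minus that gene's mean over the 12 libraries) in the 4 groups; each point is a library and each bar the group mean. The WT_tumor acute phase scores were 1.38, 0.72 and 0.83, and the WT_no_tumor scores were −1.01, −0.81 and −0.78.

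In KO livers, tumour-bearing mice had higher values of the acute phase, matrix, endothelial and ribosomal protein lists and lower values of PPARα targets by camera with the preset correlation. With an estimated correlation the adjusted p was 0.41 for each of the first 4 lists and 0.59 for PPARα targets. The matrix list had a median of 0.57 and moved with KO_tumor replicate 1, which scored 0.88 against −0.16 and 0.11 in the other KO_tumor libraries; without it the median was 0.17 (camera adjusted p = 0.0349). The acute phase list had 26 of 30 members positive with a median of 0.80, with Itih3 at 1.17 ± 0.28 and the fibrinogen chain gene Fga at 1.13 ± 0.31. PPARα targets had 15 of 20 members negative with a median of −0.78, with Cyp4a10 at −2.43 ± 0.43 and Acot3 at −1.61 ± 0.45. Endothelial markers had 16 of 16 members positive with a median of 0.42, with Clec4g, a lectin of sinusoidal endothelium, at 1.08 ± 0.22.

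By limma, 0 genes passed over all genes in this comparison, 2209 had an unadjusted p under 0.05 against 869 expected by chance, and the smallest adjusted p was 0.152 (Dcn, 1.18 ± 0.20, and Cyp4a10 among them). The excess over 869 was not tested, since the fit shares an estimate of the spread and KO_tumor holds a library that stood apart. Limma on the 6 libraries alone called 1 gene and limma with library weights 14. Adjusted over the list alone, 3 acute phase members were higher, 5 PPARα targets lower and 2 higher, and 2 endothelial markers higher. Likewise 3 matrix genes were higher (Dcn, Lum at 1.39 and Pdgfrb at 1.38), 14 ribosomal protein genes higher (Rpl23 at 1.30 among them) and 1 immediate early gene higher, Dusp1 (2.24 ± 0.48). By the same test 1 gene of the oxidative phosphorylation list, which passed as higher (median 0.32, and 0.12 with the call ended without KO_tumor replicate 1; adjusted p = 0.67 with an estimated correlation), was lower. On lists that did not pass, 2 monocyte, 2 xenobiotic, 1 bile acid, 1 amino acid and 1 mitochondrially encoded gene were lower, 2 glucocorticoid targets higher and 1 lower, and 1 neighbour of Mtdh higher.

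Of the 41 lists, 14 passed in KO livers with the preset correlation, 12 higher and 2 lower, and 0 with an estimated correlation or with fry. The balance of directions turned without KO_tumor replicate 1, the shallowest library, to 7 higher and 9 lower, with 9 of the 14 lists among them. It was 7 and 3 without KO_no_tumor replicate 2, 10 and 4 without KO_no_tumor replicate 1, 15 and 0 without KO_no_tumor replicate 3, 13 and 0 without KO_tumor replicate 2, and 10 and 5 without both libraries that stood apart. The medians of the ribosomal protein list (21 of 25 positive, 0.91), the matrix list (17 of 21, 0.57), hepatocyte core genes (16 of 19, 0.53) and the endoplasmic reticulum stress list (16 of 21, 0.54) each had an adjusted p of 0.41 with an estimated correlation. Without KO_tumor replicate 1 the medians were 0.17 for the matrix list, 0.30 for hepatocyte core genes and 0.27 for the endoplasmic reticulum stress list, whose score was 0.73 in that library and −0.18 and 0.09 in the other KO_tumor libraries. Growth hormone dependent genes had 19 of 23 members negative with a median of −0.51 (adjusted p = 0.41 with an estimated correlation). The PPARα call ended without KO_no_tumor replicate 3 or KO_tumor replicate 2 or 3, and its median was −0.49 without both libraries that stood apart (camera adjusted p = 0.02). The growth hormone call ended without KO_no_tumor replicate 3 or KO_tumor replicate 2, and the matrix call without both libraries that stood apart (median 0.10). Neutrophil markers (median 0.36, camera adjusted p = 0.222), erythroid genes (−0.11, 0.885), fatty acid oxidation (−0.22, 0.111) and lipogenesis (0.21, 0.105) did not pass. Saa1 was at −0.50 ± 1.02 (limma adjusted p = 0.84), Cd8a at −0.49 ± 1.21 (0.868), Fasn at 0.75 ± 0.69 (0.62) and Srebf1 at 0.22 ± 0.40 (0.82). Cpt1a was at −0.69 ± 0.35 (0.412), Ppara at −0.39 ± 0.32 (0.579), Rxra at 0.06 ± 0.24 (0.93) and Cyp7a1 at −0.38 ± 0.48 (0.722).

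**Figure D4:**
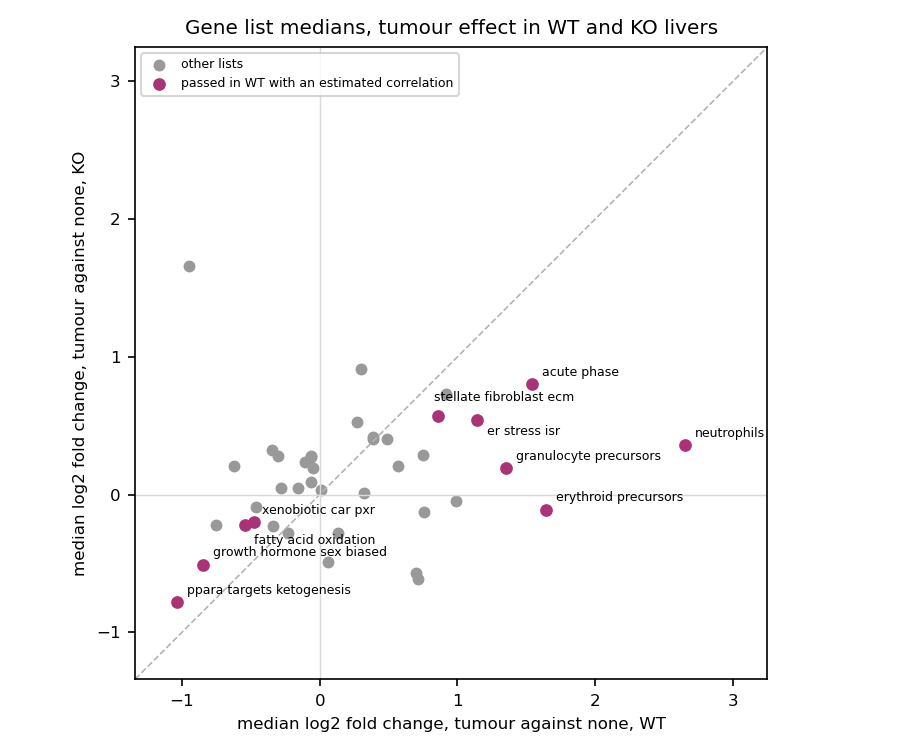
Median log2 fold change of each gene list with a tumour against without, in WT livers (horizontal) and KO livers (vertical); each point is a list, and coloured points passed in WT with an estimated correlation. The neutrophil list lies at 2.65 in WT and 0.36 in KO, and PPARα targets at −1.04 and −0.78.

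In tumour-bearing mice, KO livers had higher values than WT livers for lists of lipid synthesis, fatty acid breakdown and oxidative phosphorylation, and lower values for lists of the acute phase, endoplasmic reticulum stress and blood cells. By camera 24 of 41 lists passed with the preset correlation and 0 with an estimated correlation, with which the adjusted p of the lists so described was 0.13 to 0.36. Lipogenesis had 20 of 20 members positive with a median log2 fold change of 1.09, such as Me1, which makes NADPH for lipid synthesis (2.26 ± 0.41), the carbohydrate-sensing factor gene Mlxipl (1.04 ± 0.21) and Pnpla3 (2.22 ± 0.54). PPARα targets had 16 of 20 members positive with a median of 0.85, such as Acot3 (2.69 ± 0.45) and the fatty acid binding protein gene Fabp1 (1.93 ± 0.35). Nuclear oxidative phosphorylation genes had 20 of 21 members positive with a median of 0.66, such as Atp5b (1.14) and Uqcrc1 (0.81). These list differences passed with the preset correlation, and their adjusted p with an estimated correlation was 0.17, 0.13 and 0.13.

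Adjusted over the list alone, 8 lipogenesis genes, 10 PPARα targets and 13 oxidative phosphorylation genes were higher and 1 PPARα target lower, while 0 members of these lists passed limma over all genes. Me1 had a limma adjusted p of 0.0784 over all genes and Acot3 0.0607. Fatty acid oxidation genes had 18 of 20 members positive with a median of 0.46 (adjusted p = 0.16 with an estimated correlation), 5 of them past the test adjusted over the list alone, such as Acaa1b (1.71 ± 0.43) and Cpt2 (0.84). Lipoprotein genes had a median of 0.62 (adjusted p = 0.13 with an estimated correlation), with Apoa2 at 1.58. Retinoid genes had a median of 0.38 (adjusted p = 0.16 with an estimated correlation), with Rbp4 at 1.07, Retsat at 1.53 and Cyp26b1 at 3.44. The xenobiotic list had a median of 0.47 (adjusted p = 0.06 with an estimated correlation), the bile acid list 0.34 (0.13), the lipid droplet list 0.32 (0.13) and ribosomal protein genes 0.69 (0.18). Adjusted over the list alone, 9 lipoprotein genes were higher and 1 lower, and 7 retinoid, 9 xenobiotic, 3 bile acid, 4 lipid droplet and 5 ribosomal protein genes were higher; 0 passed limma over all genes. The preset calls of these lists, and of lipogenesis, PPARα targets and oxidative phosphorylation, were kept with every single library left out. Yet the lipid droplet median was 0.12 without WT_tumor replicate 1, 0.49 without WT_tumor replicate 2 and 0.21 without WT_tumor replicate 3, the retinoid median 0.59 without KO_tumor replicate 3, and the ribosomal protein median 0.38 without KO_tumor replicate 1.

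The acute phase list had 24 of 30 members negative with a median of −0.59 (adjusted p = 0.36 with an estimated correlation), with Steap4 at −1.14 ± 0.22, Apcs at −1.85 ± 0.40 and Saa1 at −3.90 ± 1.02 (limma adjusted p = 0.157). Endoplasmic reticulum stress genes had 17 of 21 members negative with a median of −0.50 (adjusted p = 0.14 with an estimated correlation), with Sdf2l1 at −2.40 ± 0.39 (limma adjusted p = 0.0607) and Xbp1 at −0.93 ± 0.20. Erythroid genes had a median of −1.54 (adjusted p = 0.14 with an estimated correlation) with Hbb-bs at −1.54 ± 0.42, neutrophil markers −1.80 (0.36), granulocyte precursor markers −2.04 (0.13) and monocyte markers −0.83 (0.23). Without KO_tumor replicate 2 the preset calls of the acute phase (median −0.34), endoplasmic reticulum stress (−0.50), erythroid (−1.65) and neutrophil (−1.56) lists ended, and without WT_tumor replicate 2 those of the neutrophil (−2.14) and monocyte (−0.59) lists. T and NK cell markers had a median of −0.50 (camera adjusted p = 0.84) and Cd8a was at −0.98 ± 1.21 (limma adjusted p = 0.703).

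Adipocyte markers had 4 of 5 members positive with a median of 2.33 (adjusted p = 0.16 with an estimated correlation) and moved with KO_tumor replicate 1, the library of lowest depth. Its value of Aoc3, an amine oxidase of fat tissue, was 254, against 9.11 and 18.5 in the other KO_tumor libraries, and its value of the lipid droplet gene Plin1 was 182, against 4.55 and 24.9. Adiponectin (Adipoq) was at 37, 11.7 and 2.31 in the KO_tumor libraries and listed at 0 in the WT_tumor libraries. Without KO_tumor replicate 1 the median was 1.5 and the preset call ended, as it did without WT_tumor replicate 2 (1.05) or KO_tumor replicate 3 (2.43) and with a pseudocount of 10 (1.22).

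The remaining lists past the preset threshold included hepatocyte core genes (median 0.17; adjusted p = 0.36 with an estimated correlation), growth hormone dependent genes (0.28; 0.19) and glucose production (0.15; 0.27). They also included amino acid and urea cycle genes (median 0.16; adjusted p = 0.57 with an estimated correlation), antigen presentation (0.63; 0.70), pericentral genes (0.23; 0.57) and proliferation genes (−0.96; 0.59). Their calls ended without WT_tumor replicate 1 (antigen presentation), WT_tumor replicate 2 (growth hormone, glucose production, pericentral, proliferation) or WT_tumor replicate 3 (amino acid, antigen presentation). They also ended without KO_tumor replicate 1 (hepatocyte core, amino acid, antigen presentation), KO_tumor replicate 2 (glucose production, proliferation) or KO_tumor replicate 3 (glucose production, antigen presentation, pericentral, growth hormone, proliferation). The pericentral call ended without any of the KO_no_tumor libraries. Of these lists, glucose production turned to −0.03 without WT_tumor replicate 2 and the amino acid list to −0.01 without WT_tumor replicate 3. Glucose production was also at 0.34 without WT_tumor replicate 1, 0.28 without WT_tumor replicate 3, 0.28 without KO_tumor replicate 1 and 0.02 without KO_tumor replicate 3. The amino acid list was at 0.39 without WT_tumor replicate 1, 0.38 without WT_tumor replicate 2, 0.32 without KO_tumor replicate 2 and 0.26 without KO_tumor replicate 3. Medians were 0.26 without WT_tumor replicate 3 and 0.05 without KO_tumor replicate 1 for antigen presentation, 0.04 without WT_tumor replicate 3 and 0.27 without KO_tumor replicate 2 for hepatocyte core genes, and 0.06 without WT_tumor replicate 2 and 0.05 without KO_tumor replicate 3 for pericentral genes. Growth hormone dependent genes were at 0 without WT_tumor replicate 2, 0.47 without KO_tumor replicate 1, 0.44 without KO_tumor replicate 2 and 0.04 without KO_tumor replicate 3. With quantile normalization the glucose production (0.23), proliferation (−0.62), antigen presentation, hepatocyte core and pericentral calls ended and the amino acid list was at 0.29. With a pseudocount of 10 the glucose production, antigen presentation and pericentral calls ended and proliferation was at −0.57. In total 24 of 41 lists passed, 17 higher and 7 lower (16 and 2 without KO_tumor replicate 2), with 0 past the threshold with an estimated correlation and 11 with fry. The median log2 fold change of all 17380 genes was −0.12, and 0 after quantile normalization; camera compares a list with the other genes and so works relative to that shift.

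Over all genes, limma called 2 genes higher and 2 lower in KO livers of tumour-bearing mice. Besides Mtdh, the carboxylesterase gene Ces1e (ENSMUSG00000061959, chromosome 8, 93927846 to 93956247) rose, from 479 ± 208 in WT_tumor to 1970 ± 457 in KO_tumor (SD, n = 3), a log2 fold change of 2.11 ± 0.29 (limma adjusted p = 0.0178). Its values without a tumour were 841 ± 90.5 in WT and 904 ± 16.3 in KO, and it belongs to a cluster of related carboxylesterase genes, so its share of reads is uncertain. The call ended with the 6 libraries alone (limma adjusted p = 0.215), without WT_tumor replicate 3 (0.107), without KO_tumor replicate 2 (0.0597) and without both libraries that stood apart (0.0608). Over its 22 alternatives the adjusted p lay between 0.000165 and 0.215.

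The processed pseudogene Rpl31-ps8 (ENSMUSG00000067870, chromosome 15, 90648482 to 90648859) was at 726, 130 and 208 in KO_tumor and at a mean of 0.186 in WT_tumor, below the value of 1 read (7.86 ± 0.92, limma adjusted p = 0.00528; 0.114 with the 6 libraries alone). Its KO_no_tumor mean was 47.2 ± 13.8 and its WT_no_tumor mean 0.323. Its sequence matches transcripts of Rpl31 at 100% of its bases, so its values are uncertain, and its log2 fold change depends on the pseudocount. Over its 21 alternatives the fold change ran from 4.79 to 8.38. The long non-coding RNA Gm17644 (ENSMUSG00000097171, chromosome 1, 12737787 to 12743314), outside the naming rule and named after its values were seen because the count was 4, had a mean of 102 ± 22.65 in WT_tumor and near 0 in KO_tumor (limma adjusted p = 0.0157). The Gm17644 call ended with a pseudocount of 10, with quantile normalization, with the 6 libraries alone and without WT_tumor replicate 1 or 3.

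The count of 4 genes was 210 without WT_tumor replicate 2, 9 without KO_tumor replicate 1, 8 without KO_tumor replicate 3, 7 without WT_no_tumor replicate 2, and 2 without WT_tumor replicate 3. It was 0 by limma with the 6 libraries alone and 1664 with library weights, under which KO_tumor replicate 1 had a weight of 0.14. KO_tumor replicate 3 had a weight of 3.79 and WT_tumor replicate 1 of 2.64, so 1 library in each group counted most. At an unadjusted p under 0.05 there were 2510 genes, against 869 expected by chance. The excess was not tested, since genes are correlated and KO_tumor, with its library of low weight, enters a shared estimate of the spread. Among the genes fixed for naming, Fasn, the fatty acid synthase gene, was at 1.39 ± 0.69 (limma adjusted p = 0.365) and Srebf1 at 0.26 ± 0.40 (0.766). Rxra was at 0.09 ± 0.24 (0.88), Ppara at 0.25 ± 0.32 (0.72), Cpt1a at −0.24 ± 0.35 (0.757) and Cyp7a1 at −0.39 ± 0.48 (0.701).

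Whether the tumour effect differed between genotypes was tested by the interaction term. Lists of neutrophil markers (median −2.18), erythroid genes (−2.18), monocyte markers (−1.29) and the acute phase (−0.84) had a negative interaction, that is a lower log2 tumour effect in KO than in WT, and lipogenesis (0.86), PPARα targets (0.73), oxidative phosphorylation (0.55) and fatty acid oxidation (0.50) had a positive one. Each passed with the preset correlation, as did 18 of 41 lists in all, 10 higher and 8 lower. With an estimated correlation or with fry 0 lists passed, and the adjusted p of these 8 lists with an estimated correlation was 0.22, 0.21, 0.21, 0.23, 0.27, 0.21, 0.22 and 0.26 in the order named. The lipogenesis median was 0.47 without WT_no_tumor replicate 1, 1.48 without WT_no_tumor replicate 2 and 0.57 without KO_tumor replicate 1, that of fatty acid oxidation 0.30 without WT_no_tumor replicate 2, and that of monocyte markers −0.79 without KO_tumor replicate 1 and −0.58 without both libraries that stood apart. With a pseudocount of 10 the medians were −1.10 for neutrophil markers and −1.35 for erythroid genes, and with quantile normalization −1.41 for erythroid genes. With genotype labels of the list scores permuted within each tumour state, 400 relabellings gave a smallest possible p of 0.005. Such relabelling is exact where genotype has no effect in either tumour state. It cannot fully separate an interaction from a genotype effect common to both states. By this exact permutation test the interaction had p = 0.01 for erythroid genes, 0.02 for monocyte markers, 0.025 for neutrophil markers and 0.03 for the acute phase (two-sided), each with an adjusted p of 0.308 over 41 lists. By the same exact permutation test p was 0.27 for lipogenesis and 0.22 for oxidative phosphorylation (adjusted p = 0.615), and 0.165 for PPARα targets and 0.16 for fatty acid oxidation (adjusted p = 0.536). Adipocyte markers, whose list did not pass, scored 1.65, −0.06 and 0.72 in KO_tumor and −1.24, −1.13 and −1.31 in WT_tumor. Their permutation p for the interaction was 0.135 (adjusted p = 0.536).

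By limma 0 genes passed for the interaction, with 816 at an unadjusted p under 0.05 against 869 expected by chance and a smallest adjusted p of 0.727; limma with library weights called 1. Across the 17380 genes the tumour effects in WT and KO livers, which share no library, had a Pearson r of 0.16 and a Spearman rho of 0.19. Of the 118 genes called in WT livers, 111 had the same sign in KO livers, with a median size of 1.83 in WT and of 0.66 in the same direction in KO. Since they were chosen for their size in WT, a smaller value in KO is also what selection gives.

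Averaged over both tumour states, KO livers had higher values of the xenobiotic and bile acid lists. The xenobiotic list had 19 of 23 members positive with a median of 0.46 (adjusted p = 0.013 with an estimated correlation). The bile acid list had 18 of 20 members positive with a median of 0.36 (adjusted p = 0.038 with an estimated correlation). Of each list 5 members passed adjusted over the list alone, while 0 passed limma over all genes. Nuclear oxidative phosphorylation genes had 19 of 21 members positive with a median of 0.44 (adjusted p = 0.15 with an estimated correlation), 13 of them past the test adjusted over the list alone, and lipogenesis a median of 0.64 (0.24), which was 0.40 without WT_no_tumor replicate 2. An exact permutation of list scores gave p = 0.005, the smallest it can give, for the xenobiotic list and for oxidative phosphorylation, with an adjusted p of 0.103. The same exact permutation gave p = 0.055 for the bile acid list (adjusted p = 0.282) and 0.07 for lipogenesis (0.319). Over all genes, limma called 2, Mtdh lower (−3.22 ± 0.25, adjusted p = 4.46e-05) and Rpl31-ps8 higher (6.52 ± 0.65, adjusted p = 0.000737), with 1787 at an unadjusted p under 0.05. The count was 15 without WT_tumor replicate 2, 1 among protein-coding genes alone and 139 with library weights. The averaged log2 fold change of Rpl31-ps8 ran from 3.62 to 6.79 over its 20 alternatives.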

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

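The tests in this part were fixed before their results were seen. For 18 gene lists the tumour effect differed between KO and WT livers by the interaction term with camera at the preset correlation, and 0 of them passed with an estimated correlation, where the adjusted p ranged from 0.21 to 0.66. Median interactions were positive for lipogenesis (0.86), PPARα targets (0.73), mitochondrially encoded genes (0.61), lipid droplet genes (0.58), nuclear oxidative phosphorylation genes (0.55), lipoprotein genes (0.53), fatty acid oxidation (0.50), ribosomal protein genes (0.46), growth hormone dependent genes (0.34) and retinoid genes (0.27). They were negative for neutrophil markers (−2.18), erythroid genes (−2.18), granulocyte precursor markers (−1.97), monocyte markers (−1.29), B and plasma cell markers (−1.05), proliferation genes (−0.88), the acute phase list (−0.84) and endoplasmic reticulum stress genes (−0.49). The preset calls ended without WT_tumor replicate 2 for the B and plasma cell, granulocyte precursor, growth hormone, proliferation and mitochondrially encoded lists. They ended without KO_tumor replicate 1 for the lipoprotein and mitochondrially encoded lists, without KO_tumor replicate 2 for the granulocyte precursor and endoplasmic reticulum stress lists, and without KO_tumor replicate 3 for proliferation. Without a tumour-free library, calls ended for granulocyte precursors (KO_no_tumor replicate 1), mitochondrially encoded genes (KO_no_tumor replicate 2) and proliferation (WT_no_tumor replicate 2 or 3 or KO_no_tumor replicate 3). Medians also moved by over 1.5 times with a library left out. Without WT_no_tumor replicate 1 they were 0.47 for lipogenesis and −1.39 for proliferation, without WT_no_tumor replicate 2 they were 1.48 for lipogenesis, 0.30 for fatty acid oxidation, 0.64 for retinoid genes and −0.46 for proliferation, and without WT_no_tumor replicate 3 −1.59 for B and plasma cells. Ribosomal protein genes were at 0.29 without KO_no_tumor replicate 1 and proliferation at −1.47 without KO_no_tumor replicate 2. Retinoid genes were at 0.18 without WT_tumor replicate 1. Without WT_tumor replicate 2 the medians were 0.45 for retinoid genes, 0.15 for growth hormone dependent genes, 0.27 for mitochondrially encoded genes and 0.75 for ribosomal protein genes, and without WT_tumor replicate 3 −1.84 for B and plasma cells. Without KO_tumor replicate 1 they were 0.57 for lipogenesis, 0.35 for lipoprotein genes, 0.18 for retinoid genes, −0.79 for monocytes, 0.58 for growth hormone dependent genes and 0.23 for ribosomal protein genes, and without KO_tumor replicate 3 growth hormone dependent genes were at 0.15. With a pseudocount of 10 neutrophil markers were at −1.10 and erythroid genes at −1.35, and with quantile normalization erythroid genes were at −1.41.

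A single library may produce such differences with 3 libraries per group. Without KO_tumor replicate 1, the shallowest library, 18 of the 18 lists kept their sign and at least 50% of the size of their median, which argues against this library as the sole cause. The same held for 18 without WT_no_tumor replicate 2, the library with the lowest lipogenic values. Low WT_no_tumor values lower a positive interaction, so for lists such as lipogenesis (0.86, and 1.48 without the library) this outcome was set in advance. For lists without that pattern it argues against WT_no_tumor replicate 2 as the sole cause. Without WT_tumor replicate 2 the number was 16 and without KO_tumor replicate 3 it was 17. Among 100 random splits of the libraries, 22 gave as many lists as the real split, with 24 in the highest of the others, so chance cannot be excluded, and for genes the real count was 0 and the highest other 2. A genotype-dependent response of the liver to the tumour, which the design names, remains an open hypothesis beside chance.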

How the results depend on the processing

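Settings chosen after the data were seen were the removal of both libraries that stood apart, protein-coding genes alone and the list tests under both rescalings. Across all settings, called genes kept direction and side of the threshold in 705 instances, lost the call in 171 and changed direction in 0. Called lists kept both in 1834, lost the call in 341 and changed direction in 10, while genes and lists not called passed in 254 and 128. Whole reads were not recovered for nearly all genes, so the planned edgeR and DESeq2 alternatives were not run. In the fit of tumour against none in WT, the simulated data recovered 16% of genes changed by a log2 of 1, so smaller changes were mostly below what 3 libraries per group show. The cause of the changes listed here was not tested.

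The count of genes for KO against WT without a tumour (1) was 2 with library weights and 0 to 1 with a library left out. With a tumour (4) it was 17 with a pseudocount of 10, 16 without the filter, 11 with quantile normalization, 0 with the 6 libraries alone, 9 with robust eBayes, 1664 with library weights, 9 without both libraries that stood apart, 2 among protein-coding genes and 2 to 210 with a library left out. For the tumour in WT (118) it was 510 with library weights, 212 without both libraries that stood apart and 12 to 205 with a library left out, and rescaling to the same total moved the split of 75 higher and 43 lower to 77 and 25. For the tumour in KO (0) it was 1 with the 6 libraries alone, 14 with library weights and 0 to 1 with a library left out. For the interaction (0) it was 1 with library weights and 0 to 1 with a library left out, and for the averaged comparison (2) it was 139 with library weights, 1 among protein-coding genes and 2 to 15 with a library left out.

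In the order KO against WT without and with a tumour, tumour in WT and in KO, interaction and average, the counts of lists (14, 24, 27, 14, 18 and 18) were 0, 0, 10, 0, 0 and 2 with an estimated correlation and 0, 11, 13, 0, 0 and 2 with fry. They were 12 to 17, 18 to 25, 23 to 29, 10 to 16, 15 to 21 and 16 to 24 with a library left out. Interferon genes in KO against WT without a tumour ran from −0.01 to 1.12 with a library left out and were at −0.01 without both libraries that stood apart, and in the average ran from −0.06 to 0.71 and were at −0.06. With a library left out, glucose production ran from −0.03 to 0.34 with a tumour and from −0.02 to 0.18 in the average, and amino acid and urea cycle genes from −0.01 to 0.39 with a tumour. For the tumour in WT, cholesterol synthesis ran from −0.04 to 0.61, B and plasma cell markers from −0.05 to 1.32 and glucocorticoid targets from −0.11 to 0.85. Quantile normalization moved the median log2 fold change of all genes from −0.12 to 0 for KO against WT with a tumour and from −0.09 to 0.02 for the interaction.

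The replicate numbers of the sample titles showed no pairing: of 18 pairs with the same number 0 had a correlation of deviations over 0.1 (−0.094 to 0.1), and 3 of 12 libraries correlated best with their own number. The deposited columns number some KO_no_tumor libraries differently, and that numbering was not tested as a whole. KO_no_tumor replicate 2, numbered 3 there, had 0.146 with WT_no_tumor replicate 3, the highest of all pairs between groups. It had −0.031 with WT_tumor replicate 3 and 0.067 with KO_tumor replicate 3. With the replicate number of the titles as a block the gene counts were 1, 13, 89, 0, 0 and 2 and the list counts 15, 22, 27, 15, 18 and 18.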

Other observations

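The tests of Rpl31 expression, of a chromosome 15 segment and of counts of genes other than Mtdh were chosen after the result was seen, as were the genes described first. Some genes differed widely between livers of the same group. Dbp, a clock output gene, was at 781, 736 and 2.84 in the WT_no_tumor libraries and at 923, 44.4 and 785 in the KO_no_tumor libraries, and the clock gene Per1 at 443, 430 and 33.1 in WT_no_tumor. The circadian list did not pass in WT livers with a tumour (median −0.46, camera adjusted p = 0.109). Fasn was at 17900 in WT_no_tumor replicate 2 against 149000 and 156000 in the other libraries of that group, and the desaturase gene Scd1 at 450000 against 2120000 and 1450000, with a lipogenesis score of −1.11 in that library. Hamp, the iron hormone hepcidin, was at 31, 5890 and 64.2 in the WT_tumor libraries.

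Averaged over tumour states, the KO and WT values of 72 of 17380 genes (0.414%) did not overlap, against 0.216% by chance. Genes are correlated and this count was not taken over other splits of the libraries, so whether it exceeds chance was not tested. Besides Mtdh and Rpl31-ps8, none of the 72 genes passed limma over all genes. The calcium-binding protein gene Anxa4 was at −0.70 ± 0.15 (SE; limma adjusted p = 0.342), and Ndufa8 of respiratory complex I (0.67 ± 0.16), the glycogen phosphorylase gene Pygl (0.56 ± 0.14) and Acsf2 (0.55 ± 0.12) were at positive values with the same adjusted p. A gene model inside Mtdh, 9930017N22Rik (chromosome 15, 34127090 to 34130834), was at 29.4 to 133 in WT and 0 to 9.78 in KO libraries (−4.66 ± 0.77, limma adjusted p = 0.171), and reads of it cannot be told from reads of Mtdh introns.

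Rpl31-ps8 was read in each KO library (34.9 to 726) and below 1 read in each WT library (at most 0.769). Rpl31 itself had an averaged log2 fold change of 0.07 (95% interval −0.47 to 0.61). Reads of Rpl31 placed on the pseudogene would be missing from this value, so it cannot decide on higher expression of Rpl31. The pseudogene matched Rpl31 transcripts at 378 of 378 bases (100%), so reads of Rpl31 may be placed on it, which leaves open why this occurred in KO libraries. The test for a segment carried along with the knockout covered all of chromosome 15, so a short segment near Mtdh would be diluted in it. With Mtdh and 9930017N22Rik left out, genes without overlap were not detectably more frequent on chromosome 15, which also holds Mtdh (4 of 646, Rpl31-ps8 being 1 of the 4, against 66 of 16732; Fisher's exact p = 0.333, odds ratio 1.57, 95% interval 0.415 to 4.24), nor with Rpl31-ps8 left out as well (3 of 645; p = 0.743, odds ratio 1.18, 95% interval 0.237 to 3.62). These intervals leave a segment carried along with the knockout open, as do the genes near Mtdh: Tspyl5 (chromosome 15, 33684021 to 33688030) was at 207 to 393 in KO and 117 to 196 in WT libraries (0.77 ± 0.24, limma adjusted p = 0.386), while the list of 12 neighbours had a median of −0.08 with 5 positive and 7 negative (camera adjusted p = 0.774; fry for change in either direction, adjusted p = 0.0219), and a sequence difference between the mouse lines was not tested. The other genes without overlap on chromosome 15 were Nudcd1 (−0.62 ± 0.15) and Ywhaz (−0.15 ± 0.11).

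KO_tumor replicate 1 stood apart from the other 11 libraries. Low depth alone may not account for this: among 3769 genes with a mean of at least 1000, its mean correlation with the others was 0.808, against 0.868 to 0.916. Across the 98.9% of genes with a known transcript, its deviation had a Spearman rho of −0.01 with transcript length, which argues against a length bias as the whole cause. With GC content rho was 0.27, and WT_no_tumor replicate 2 had the larger size (−0.34). That library also had the lowest correlation of the other 11 (0.868), while KO_tumor replicate 3 had a rho of 0.22 and a correlation of 0.909. These values do not decide on a GC bias. No biological explanation was tested, and fat tissue in the sample, given its adipocyte markers, and RNA quality remain open. The adipocyte score was 1.65 in KO_tumor replicate 1 and 1.3 in KO_no_tumor replicate 2. Over all tested genes KO_no_tumor replicate 2 had the highest mean correlation with the other libraries (0.926), so adipocyte markers alone did not set a library apart.

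The 10 splits of a pair of groups of 3 are too few for a share under 0.05. The real count of genes and the highest of the other splits were 1 and 1 for KO against WT without a tumour, 4 and 1 with a tumour, 118 and 0 for the tumour in WT and 0 and 1 for the tumour in KO. For lists they were 14 and 14, 24 and 23, 27 and 23, and 14 and 18. The other splits called a median of 12, 13, 18 and 9 lists for these pairs, 13 for the interaction and 12 for the average. As many as the real count came from 3, 1, 1 and 10 splits for genes and from 3, 1, 1 and 4 for lists, the real split included. For the interaction all 100 of 100 random splits gave at least 0 genes. For the averaged comparison 1 of 100, the real one, gave 2 genes, with 1 in the highest of the others, but 1 of the 2 genes is Mtdh, whose fall the knockout fixes, so that count tells nothing about chance. For genes other than Mtdh, 6 of the 100 splits gave as many as the real count of 1 (Rpl31-ps8), with 1 in the highest of the others, and 18 gave as many lists as the real 18, with 23 in the highest of the others, so chance cannot be excluded for either. Without Mtdh, the real count and the highest other were 0 and 1 for KO against WT without a tumour (10 of 10 splits gave as many) and 3 and 1 with a tumour (1 of 10).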
